A study of Homo sapiens with 9 samples.

How the data were processed

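RNA was measured in 9 libraries of one line of human dermal fibroblasts, 3 per group. Per the labels, cells were grown in 10% serum, starved for 12 h in 0.5% serum, pretreated for 12 h and stimulated for 72 h, in control medium, with 10 ng/mL of TGF-β1, or with TGF-β1 and 30 µM of II559. No group received II559 without TGF-β1, and the labels do not say whether control cells and cells given TGF-β1 alone received the compound's solvent, so that its effect is part of the II559 comparison if they did not, or whether replicates were separate cultures. The libraries were poly(A)-selected, stranded and sequenced as paired reads of 150 bases in what the labels describe as a single batch. The deposited file holds expected counts per gene made by the authors with STAR and RSEM on GRCh38, without scaling between libraries; tool versions, the annotation release and the strand setting are not stated. Between 5.22 and 5.95% of its values per library have decimals.

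Expected counts were rounded to whole numbers. Totals per library ranged from 47518195 to 61697351 counts. Of 78932 genes, 36187 carry no symbol and were kept, 34032 had at least 1 count and 17523 passed edgeR's filterByExpr by group (minimum count 10, minimum total count 15); these held 99.948 to 99.967% of the counts. Gene positions, lengths and GC content came from GENCODE release 29 on GRCh38 by gene identifier, which gave GC content and length for 16406 of the 17523 genes. CPM are relative to the library total scaled by TMM factors, which averaged 1.12 in control, 0.937 in TGF-β1 and 0.950 in TGF-β1 with II559. The common biological coefficient of variation was 3.65%. The replicate numbers did not pair the libraries: none of the 9 matched best with its own number in another group, with correlations of −0.0619 to 0.00959 for same-number pairs.

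The 3 groups were fitted together with edgeR 4.0.16 in R 4.3.3 (TMM, robust glmQLFit, quasi-likelihood F test, two-sided), and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The contrasts were TGF-β1 against control, TGF-β1 with II559 against TGF-β1, and TGF-β1 with II559 against control. Standard errors are Wald errors from that fit, not below counting error. A fold bound against a group at 0 counts uses a floor of 3 counts over the group, and ratios with 1 to 3 counts carry exact 95% intervals; both cover counting error only. The comparison of the first 2 contrasts was set beside 20 simulated data sets without an II559 effect and beside the overlap of independent lists.

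A total of 33 gene lists were fixed from general knowledge before the data were examined, as were the comparisons, the tests of genes and lists, the rules for named genes and most alternatives. They cover TGF-β targets, collagen chains, collagen processing, matrix glycoproteins, contractile genes, matrix proteases, the methionine cycle, NAD, histone and DNA methylation enzymes, inflammation, interferon, the cell cycle, SREBP, ATF4, the unfolded protein response, NRF2, metallothioneins, p53, glycolysis and hypoxia, oxidative phosphorylation, adipogenic genes, fibroblast identity, Wnt with Notch and Hedgehog, YAP, lineage factors, lysosomes, markers of 5 other kinds of cells, and mitochondrial and ribosomal protein mRNAs as signs of RNA quality. Each list was tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists of a contrast), again with an estimated correlation, and with fry, from edgeR and limma 3.58.1. Camera compares a list with the other genes, while fry tests only whether a list's genes move one way on balance. Named genes are the 8 largest rises and falls in each of the first 2 contrasts and the 3 largest in the third (called, at least 5 CPM over all libraries, group ranges not overlapping, protein coding), most of a fixed panel of 14 genes, up to 4 of the called members of each list with the largest change, and 6 genes moved opposite ways and 4 moved the same way by TGF-β1 and II559.

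Alternatives were RLE and upper quartile scaling, no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, each library left out in turn, only the 2 groups compared, adjusted p under 0.01 and a test against a fold change of 1.5 (glmTreat). Chosen after seeing the data were offsets for GC content and length (smooth curves per library, mgcv 1.9.3), counts left unrounded, upper quartile scaling for the lists, and list counts without TGF-β1 with II559 replicate 3. The tests were tried on simulated data of the same depth, with 50 genes changed at each size. These were far fewer than the genes called in the real comparisons, so rates there may differ. For TGF-β1 with II559 against TGF-β1, edgeR recovered 34% of genes changed by 0.2 on the log2 scale, 62% at 0.5, 78% at 1 and 92% at 2, with 7 false calls, and for TGF-β1 against control 42%, 66%, 80% and 94% with 12 false calls. A GC and length trend, planted between libraries at a size not matched to the real data, gave 732 calls without offsets and 1 with them. The offsets model the same variables as the planted trend, so few calls with them were likely from the start. Genes linked to the sex chromosomes that could bear on the donor were left out of the text.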

Results

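Poly(A) RNA was sequenced from one line of human dermal fibroblasts in 3 groups of 3 libraries. The control cells received neither agent, the second group received 10 ng/mL of TGF-β1, a cytokine that turns fibroblasts into matrix-producing myofibroblasts, and the third group received TGF-β1 with 30 µM of II559, a compound described as an inhibitor of NNMT (nicotinamide N-methyltransferase, which methylates nicotinamide). The libraries held a total of 53187733, 54357778 and 60744648 counts in control replicates 1 to 3, 47518195, 53592263 and 58099219 in TGF-β1, and 61697351, 52181874 and 59529299 in TGF-β1 with II559, over 78932 genes. A total of 17523 genes had enough counts to be tested. The first principal component of the 9 libraries held 77.7% of the variance and parted the control libraries from the 6 others. TGF-β1 with II559 replicate 3 stood apart from the other libraries of its group: the chi-square per degree of freedom between 2 libraries was 18.8 and 14.7 for the pairs that held it and 2.13 to 3.73 for the other pairs within groups. Levels are given in CPM (counts relative to the TMM-scaled library total), mean ± SD with n = 3, changes as log2 fold change ± SE from the fit to all 9 libraries, and positions on GRCh38.

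TGF-β1 against control asked which genes respond to the cytokine. The largest rises among protein-coding genes of at least 5 CPM whose group ranges did not overlap were in KANK4 (ENSG00000132854; chromosome 1, 62236979 to 62319414), from 0.0776 ± 0.0352 to 24.7 ± 0.724 CPM, 303-fold, and in COMP, a cartilage and tendon matrix protein (ENSG00000105664; chromosome 19, 18782773 to 18791314), from 0.718 ± 0.169 to 169.7 ± 3.03 CPM, 234-fold. CHRNA9, IGF1, ISLR2, PLN, KCNH1 and NOX4 followed, with log2 fold changes of 7.80, 7.16, 6.87, 5.95, 5.72 and 5.51. ADH1B, an alcohol dehydrogenase (ENSG00000196616; chromosome 4, 99304964 to 99352760), fell from 18.2 ± 0.574 CPM to 0 counts in all 3 TGF-β1 libraries, at least 904-fold lower with 3 counts over the group taken as the floor. SLC7A14, COL21A1, GDF5, GRIA1, ACKR4, CHRDL1 and SECTM1 were the next largest falls, with log2 fold changes of −8.58, −7.06, −6.71, −5.97, −5.82, −5.75 and −5.69.

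NNMT itself (ENSG00000166741; chromosome 11, 114257787 to 114313285) rose 4.86-fold with TGF-β1, from 86.7 ± 1.09 to 422 ± 5.02 CPM. ACTA2, the smooth muscle actin that marks myofibroblasts (ENSG00000107796; chromosome 10, 88935074 to 88991339), rose 6.25-fold, from 399 ± 8.78 to 2493 ± 16.8 CPM, and TAGLN rose 3.5-fold. CCN2 rose 15.3-fold, IL11 15.4-fold, SMAD7 4.14-fold and IL6 3.61-fold. COL1A1, the main chain of type I collagen (ENSG00000108821; chromosome 17, 50183289 to 50201632), rose 2.69-fold, from 13308 ± 315 to 35842 ± 103 CPM, and FN1 (fibronectin) rose 3.26-fold, from 16479.8 ± 153 to 53662 ± 473 CPM. The rises of POSTN, COL3A1 and COL1A2 were 2.65-, 1.5- and 1.47-fold. MMP1, an interstitial collagenase, was 5.21-fold lower, at 72.1 ± 0.818 CPM against 376 ± 6.75 CPM in control.

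**Figure D1:**
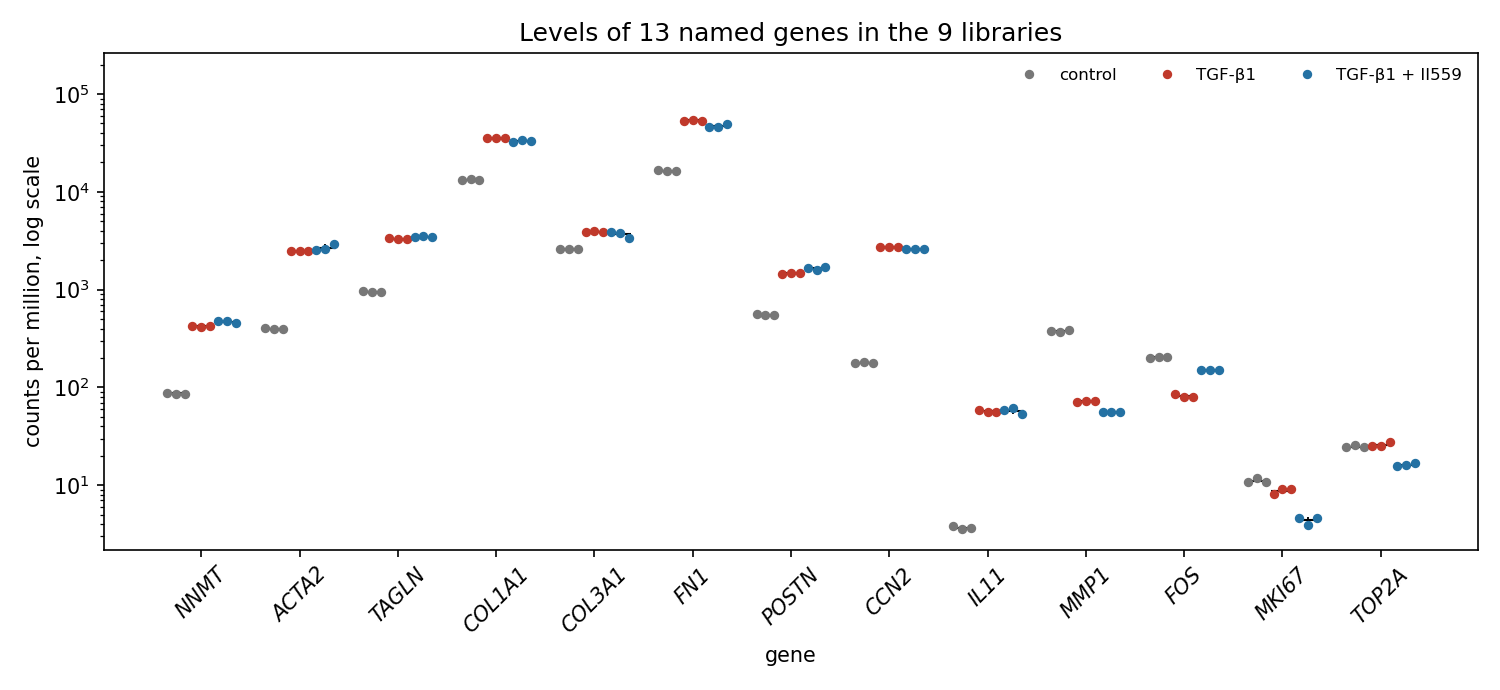
CPM on a log axis for 13 genes in the 9 libraries, 3 points per group, with a dash at the mean and bars of 1 SD that are smaller than the points for most genes. The TGF-β1 libraries lie far from control for the matrix and myofibroblast genes other than COL3A1, which rose less. The libraries with II559 lie close to those with TGF-β1 alone except for FOS, MMP1, MKI67 and TOP2A.

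Among the TGF-β target and feedback genes, 26 of 31 rose and 4 fell with TGF-β1 (median log2 fold change 1.61, camera adjusted p = 1.24e-51). Examples were NOX4 at 5.51 ± 0.10, TSPAN2 at 5.31 ± 0.07 and LDLRAD4 at 4.50 ± 0.10. The contractile and cytoskeletal genes of myofibroblasts rose in 28 of 30 cases and fell in 2 (median 1.10, camera adjusted p = 8.95e-33). Members included CDH2 (N-cadherin) at 3.51 ± 0.03, CNN1 (calponin) at 2.98 ± 0.04 and TPM1 (tropomyosin) at 2.98 ± 0.02. Collagen chains went both ways: 17 of 25 rose, COL10A1 by 4.39 ± 0.09 and COL4A1 by 3.39 ± 0.03, and 8 fell, COL14A1 at −4.72 ± 0.07. The median of the collagens was 0.94 (camera adjusted p = 1.34e-07, adjusted p = 0.175 with an estimated correlation). Collagen processing and crosslinking genes rose in 19 of 28 cases and fell in 8 (median 0.28, camera adjusted p = 2.89e-05). Among them were PLOD2, a lysyl hydroxylase, at 2.94 ± 0.03 and LOXL2, a lysyl oxidase, at 2.27 ± 0.03. Matrix glycoproteins and proteoglycans rose in 22 of 31 cases, and 9 fell, among them TNXB at −5.33 ± 0.06, PRELP at −4.53 ± 0.07 and OGN at −4.07 ± 0.07 (median 1.20, camera adjusted p = 0.000382, adjusted p = 0.0779 with an estimated correlation). Matrix proteases and inhibitors split into 13 higher and 12 lower of 28, with ADAM12 at 3.96 ± 0.03 and ADAM19 at 2.67 ± 0.03 (camera adjusted p = 0.706). YAP and mechanosensitive genes rose in 20 of 26 cases and fell in 4 (median 0.82, camera adjusted p = 1.82e-10). Examples were ANKRD1 at 5.18 ± 0.24 and IGFBP3 at 3.80 ± 0.02.

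Metabolic and stress genes also moved with TGF-β1. Glycolysis and hypoxia genes rose in 27 of 30 cases and fell in 3 (median 1.35, camera adjusted p = 4.45e-25). Members included the phosphofructokinase PFKP at 3.08 ± 0.03 and the glucose transporter SLC2A1 at 2.27 ± 0.03. Genes of the amino acid response that depends on ATF4 rose in 35 of 36 cases, with the other member not passing the test (median 0.88, camera adjusted p = 1.55e-26); the amino acid transporter SLC7A5 rose by 2.62 ± 0.03 and TRIB3 by 1.98 ± 0.03. Chaperones and genes of the unfolded protein response rose in 21 of 25 cases and fell in 2 (median 0.46, camera adjusted p = 6e-07). Among them were ERN1 at 1.38 ± 0.05 and HYOU1 at 1.18 ± 0.03. In the methionine cycle, one-carbon and polyamine list, 13 of 26 rose, such as MTHFD2 at 1.47 ± 0.03 and CBS at 0.98 ± 0.03, and 7 fell (camera adjusted p = 0.0979). Of 26 NAD and nicotinamide genes, 5 rose, NNMT most of all, and 14 fell, including QPRT at −1.75 ± 0.04 and NT5E at −1.29 ± 0.03 (camera adjusted p = 0.161). Histone and DNA methylation enzymes rose in 30 of 47 cases and fell in 7 (median 0.22, camera adjusted p = 0.00709, adjusted p = 0.125 with an estimated correlation). Examples were TET3 at 2.02 ± 0.04 and SMYD3 at 1.19 ± 0.05. Genes of cholesterol and fatty acid synthesis split into 10 higher and 13 lower of 33, with LSS (lanosterol synthase) at −1.70 ± 0.03 (median 0.02, mean −0.07, camera direction down, camera adjusted p = 0.601). Cell cycle and replication genes split into 10 and 11 of 40 (median −0.02, camera adjusted p = 0.882). CCNA2 was at 1.09 ± 0.06. No direction as a set was called for oxidative stress genes (12 higher and 13 lower of 29; SOD3 at −3.56 ± 0.07), p53 targets (12 and 12 of 25; TP53I3 at 2.40 ± 0.06), nuclear-encoded oxidative phosphorylation genes (13 and 10 of 38; CYCS at 1.04 ± 0.05) or metallothioneins and zinc response genes (4 and 1 of 6; MT2A at 1.38 ± 0.04), with camera adjusted p of 0.434, 0.292, 0.701 and 0.0563. The metallothionein list was called up by camera in 5 of its alternatives, 4 with a library left out and the replicate block (camera adjusted p from 0.0268 to 0.0485).

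Adipogenic and lipid storage genes fell in 17 of 19 cases and rose in 2 (median −1.73, camera adjusted p = 0.000382, adjusted p = 0.0522 with an estimated correlation). Among them were the fatty acid binding protein FABP4 at −4.14 ± 0.27 and APOD at −3.43 ± 0.17. Dermal fibroblast identity and subset genes fell in 23 of 28 cases and rose in 4 (median −0.88, camera adjusted p = 3.57e-08). Examples were APCDD1 at −4.55 ± 0.06 and, among the rises, IGFBP3 at 3.80 ± 0.02. Interferon-stimulated genes fell in 27 of 36 cases and rose in 4 (median −0.97, camera adjusted p = 0.000249). Members included IFIT1 at −2.63 ± 0.07 and PSMB9 at −2.93 ± 0.18. Inflammatory cytokine and NF-κB genes had 14 falls and 5 rises in 21, from TNFRSF11B (osteoprotegerin) at −4.40 ± 0.07 to LIF at 4.19 ± 0.07 (median −0.83, camera adjusted p = 0.274). Lysosome and autophagy genes fell in 16 of 30 cases and rose in 9 (median −0.16, camera adjusted p = 0.0183, adjusted p = 0.0705 with an estimated correlation). The acid lipase LIPA was at −1.48 ± 0.03. Lineage and immediate-early transcription factors rose in 19 of 32 cases and fell in 12 (median 0.47, the same with FOXS1 at its bound, camera adjusted p = 0.000633, adjusted p = 0.18 with an estimated correlation). SCX rose by 4.12 ± 0.19, and FOXS1, at 0 counts in control, was at least 114-fold higher. Wnt, Notch and Hedgehog genes had 16 rises and 12 falls in 30, with FZD8 at 4.34 ± 0.04 and WNT2B at −3.85 ± 0.12 (camera adjusted p = 0.666).

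Markers of other skin cells were mostly near the limit of detection, except those of pericytes and vascular smooth muscle. Of these, 7 of 10 reached 1 CPM in each group, with a summed level of 240 ± 1.90 CPM in control and 556 ± 2.84 CPM in TGF-β1. Of 14 keratinocyte and epithelial markers 5 could be tested, and their summed level of 97.3 ± 2.34 CPM in control and 502 ± 1.82 CPM in TGF-β1 was mostly DSP (desmoplakin), which rose from 67.5 ± 0.276 to 471 ± 0.942 CPM, while 2 fell. The median of these markers was −0.69, the mean 0.04 and the camera direction up (adjusted p = 0.0388), a call that ended with an estimated correlation (adjusted p = 0.125) and without control replicate 1 (adjusted p = 0.0564) or control replicate 2 (adjusted p = 0.0574). Pericyte and vascular smooth muscle markers rose in 5 of 8 cases and fell in 2 (median 0.90, camera adjusted p = 0.00522, adjusted p = 0.0583 with an estimated correlation). Examples were MCAM at 2.70 ± 0.03 and RGS5 at −2.77 ± 0.13. Of the endothelial markers 4 were tested, 2 higher and 1 lower, and ERG, with 394 counts in TGF-β1 and 1 in control, had a ratio of 499.9 (95% counting interval 89.2 to 19796). Leukocyte markers had 1 rise and 3 falls in 4, with CD68 from 45.5 ± 0.36 to 14.9 ± 0.798 CPM, and melanocyte and Schwann cell markers 2 rises and 2 falls in 6, with MITF from 21.8 ± 0.989 to 4.4 ± 0.392 CPM. The melanocyte list had a median of −0.44, a mean of 0.50 and a camera direction down. The last 3 lists had camera adjusted p of 0.434, 0.29 and 0.434. Of the lists chosen to follow RNA quality, cytosolic ribosomal protein mRNAs fell in 29 of 38 cases (median −0.18, camera adjusted p = 0.0111, adjusted p = 0.368 with an estimated correlation). Mitochondrially encoded mRNAs fell in 4 of 13 cases (median −0.27, camera adjusted p = 0.434). MT-ND6 was at −0.59 ± 0.08. Without TGF-β1 with II559 replicate 3 the mitochondrially encoded mRNAs were called down (camera adjusted p = 0.0101 at the preset correlation). Before TMM scaling, mitochondrial genes held 3.38 ± 0.048% of counts in control and 2.28 ± 0.0351% in TGF-β1. With that scaling the 13 mRNAs summed to 25112 ± 297 CPM in control and 19793 ± 331 CPM in TGF-β1.

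In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 12051 of 17523 genes were called between TGF-β1 and control, 5923 higher and 6128 lower, and 1305 and 2040 of them changed at least 2-fold. With upper quartile scaling 40.3% of the called genes were higher, so the balance of rises and falls depends on the scaling. The median size of the change among called genes was 0.54 on the log2 scale. Adjusted over the list alone, the counts given for the lists changed by 1 gene in NAD genes (15 lower), methylation enzymes (31 higher), inflammatory genes (6 higher) and cell cycle genes (9 higher), and were the same for the other lists. Against a fold change of 1.5 the test called 4129 genes. All p-values measure the spread between these libraries only, since nothing states whether the replicates were separate cultures.

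TGF-β1 with II559 against TGF-β1 alone asked what differs with the compound in stimulated cells. Among protein-coding genes of at least 5 CPM whose group ranges did not overlap, the largest rises were in the immediate-early transcription factor genes FOS (ENSG00000170345; chromosome 14, 75278774 to 75282230), from 81.8 ± 3.15 to 149.7 ± 0.425 CPM, 1.83-fold, and FOSB (ENSG00000125740; chromosome 19, 45467995 to 45475179), from 5.84 ± 0.367 to 10.6 ± 1.21 CPM, 1.83-fold. ARHGAP28, NDUFA4L2, LXN, EGR1, OMD and ZNF829 followed, at 0.57 ± 0.11, 0.56 ± 0.06, 0.47 ± 0.09, 0.46 ± 0.05, 0.45 ± 0.07 and 0.43 ± 0.08. By the same limits, the largest falls were in the interferon-stimulated gene IFI6 (ENSG00000126709; chromosome 1, 27666061 to 27672218), from 10.7 ± 0.609 to 5.25 ± 1.19 CPM, 2.03-fold, and in the proliferation marker MKI67 (ENSG00000148773; chromosome 10, 128096659 to 128126385), from 8.76 ± 0.492 to 4.38 ± 0.365 CPM, 2-fold. RRM2, CIT, KRT19, CENPF, TOP2A and CCNB1 fell by similar amounts, with log2 fold changes of −0.80 ± 0.08, −0.79 ± 0.09, −0.75 ± 0.13, −0.75 ± 0.07, −0.68 ± 0.05 and −0.68 ± 0.07.

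The myofibroblast and matrix genes that TGF-β1 had raised moved little with II559. NNMT rose by 0.16 ± 0.03, to 472 ± 17.5 CPM from 422 ± 5.02 CPM (adjusted p = 0.000816 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). ACTA2 was at 2692 ± 207 CPM with II559 and 2493 ± 16.8 CPM without (0.11 ± 0.04, not called). COL1A1 fell by 0.12 ± 0.02, to 32939.8 ± 861 CPM, a call that ended once GC content and transcript length were corrected for (−0.05, adjusted p = 0.054 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and FN1 fell by 0.19 ± 0.02, to 46894 ± 1686 CPM. POSTN rose by 0.17 ± 0.03, MMP1 fell by 0.36 ± 0.03, and COL1A2, COL3A1, SMAD7, IL6 and IL11 did not pass the test, with log2 fold changes of −0.16 ± 0.07, −0.09 ± 0.05, −0.07 ± 0.04, −0.09 ± 0.08 and 0.03 ± 0.04. Replicate 3 of the II559 group lay apart for some of these genes. COL1A2 was at 21314, 21378 and 17821 CPM in replicates 1 to 3 with II559, all below the 22282 to 22703 CPM of TGF-β1. ACTA2 was at 2529, 2622 and 2925 CPM in those replicates, and COL3A1 and SMAD7 were lowest in replicate 3. For these genes, not passing the test is no evidence of no change. TAGLN (0.07 ± 0.02, adjusted p = 0.0495) and CCN2 (−0.07 ± 0.02, adjusted p = 0.0374) lay near the threshold of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and leaving out single libraries ended both calls: for TAGLN each library but TGF-β1 with II559 replicate 3 (adjusted p from 0.0565 to 0.176), and for CCN2 each library but TGF-β1 with II559 replicates 1 and 3 (adjusted p from 0.0596 to 0.14, in the same test).

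Cell cycle and replication genes fell together with II559: 29 of 40 fell and the other 11 did not pass the test (median −0.52, camera adjusted p = 7.01e-45, adjusted p = 0.000124 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, was at −1.01 ± 0.13, the spindle checkpoint kinase BUB1B at −0.93 ± 0.11 and the mitotic kinase AURKB at −0.83 ± 0.15. Cholesterol and fatty acid synthesis genes, which SREBP factors drive, fell in 26 of 33 cases with the other 7 not called (median −0.15, camera adjusted p = 1.11e-25, adjusted p = 0.00164 with an estimated correlation). Among them were LPIN1 at −0.32 ± 0.03 and the fatty acid synthase FASN at −0.29 ± 0.03. Interferon-stimulated genes fell in 13 of 36 cases and rose in 2 (median −0.11, camera adjusted p = 4.2e-07, adjusted p = 0.00692 with an estimated correlation). MX1 fell from 3.25 ± 0.202 to 1.24 ± 0.203 CPM. OAS1 had 21 counts without and 2 with II559, a ratio of 11.6 (95% counting interval 2.83 to 102), and its call ended without TGF-β1 replicate 2 (adjusted p = 0.161) or without TGF-β1 with II559 replicate 1 (adjusted p = 0.0746) or 2 (adjusted p = 0.0777) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Matrix proteases and inhibitors fell in 14 of 28 cases with the other 14 not called (median −0.10, camera adjusted p = 1.32e-07, adjusted p = 0.00692 with an estimated correlation). Members included MMP10 at −0.51 ± 0.10, MMP11 at −0.34 ± 0.04 and MMP3 at −0.26 ± 0.05. Lysosome and autophagy genes fell in 11 of 30 cases (median −0.07, camera adjusted p = 3.84e-05, adjusted p = 0.0156 with an estimated correlation). Among them were the protease CTSD at −0.16 ± 0.03 and the cholesterol transporter NPC1 at −0.15 ± 0.03. Unfolded protein response genes fell in 4 of 25 cases (median −0.05, camera adjusted p = 0.002, adjusted p = 0.0499 with an estimated correlation). SEC24D was at −0.13 ± 0.03.

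**Figure D2:**
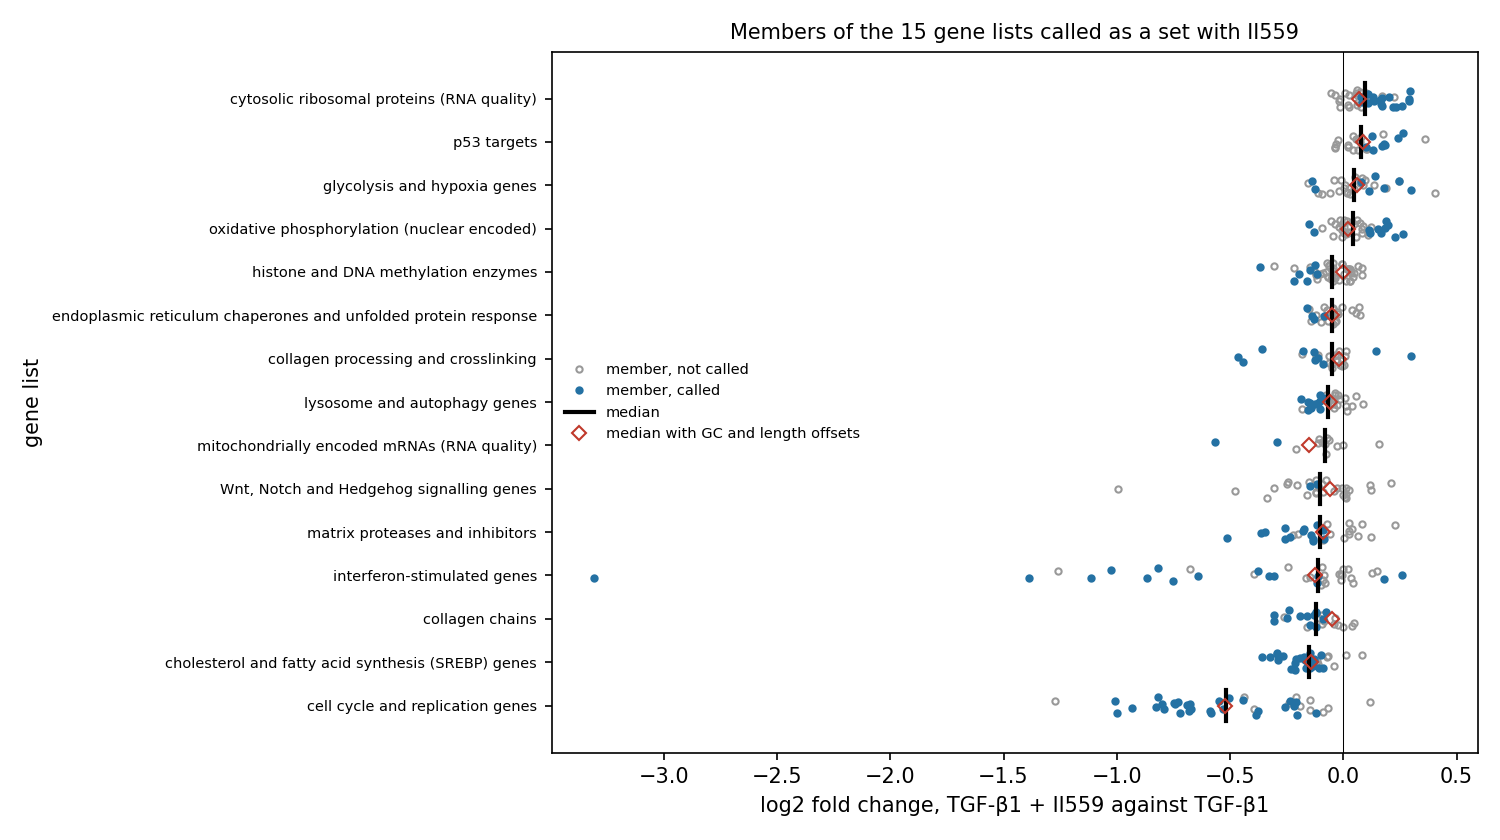
Log2 fold change with II559 in TGF-β1-treated cells for each member of the 15 gene lists called as a set, with filled points for called members, a bar at the median and a diamond at the median after GC and length correction. The cell cycle list has the lowest median (−0.52), and the leftmost point, OAS1, is a fitted value from 2 and 21 counts.

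Collagen chains fell in 13 of 25 cases with the other 12 not called (median −0.12, camera adjusted p = 7e-10, adjusted p = 0.134 with an estimated correlation). Members included COL13A1 at −0.31 ± 0.07, COL18A1 at −0.25 ± 0.04 and COL6A3, from 9400.1 ± 61.4 to 7966 ± 204 CPM. With GC and length corrected for, 5 collagens fell and the median was −0.05 (camera adjusted p = 0.000801). Collagen processing and crosslinking genes had 8 falls and 2 rises in 28 (median −0.05, camera adjusted p = 0.0016, adjusted p = 0.0566 with an estimated correlation). Among them were the transglutaminase TGM2 at −0.36 ± 0.03 and the prolyl hydroxylase P4HA1 at 0.30 ± 0.03. With GC and length corrected for, 5 of these genes fell and the median was −0.02 (camera adjusted p = 0.0263 at the preset correlation). Histone and DNA methylation enzymes fell in 7 of 47 cases, UHRF1 at −0.37 ± 0.06, NSD2 at −0.22 ± 0.03 and DNMT1 at −0.20 ± 0.04 (median −0.05, camera adjusted p = 0.000637, adjusted p = 0.0634 with an estimated correlation), and the call as a set ended with GC and length corrected for (median −0.00, camera adjusted p = 0.244). Wnt, Notch and Hedgehog genes fell in 2 of 30 cases, WNT5B at −0.15 ± 0.03 (median −0.10, camera adjusted p = 0.0295, adjusted p = 0.0848 with an estimated correlation), a call that ended with that correction (camera adjusted p = 0.155) and without TGF-β1 with II559 replicate 1 (camera adjusted p = 0.0709) or 2 (camera adjusted p = 0.0623). p53 targets rose in 8 of 25 cases, BTG2 by 0.26 ± 0.05 and the death receptor FAS by 0.24 ± 0.04 (median 0.08, camera adjusted p = 2.12e-05, adjusted p = 0.0566 with an estimated correlation). Glycolysis and hypoxia genes had 6 rises and 2 falls in 30, with BNIP3 at 0.25 ± 0.03, TPI1 at 0.18 ± 0.02 and LDHA at 0.14 ± 0.02 (median 0.05, camera adjusted p = 0.0097, adjusted p = 0.0566 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes had 9 rises, COX7B at 0.26 ± 0.04 and UQCRB at 0.23 ± 0.04 among them, and 2 falls in 38 (median 0.04, camera adjusted p = 0.00504, adjusted p = 0.421 with an estimated correlation). That call ended with GC and length corrected for (camera adjusted p = 0.224) and without TGF-β1 with II559 replicate 2 (camera adjusted p = 0.132).

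The lists that follow RNA quality moved with II559 as well. Cytosolic ribosomal protein mRNAs rose in 17 of 38 cases, RPL37 by 0.30 ± 0.05 and RPS27 by 0.29 ± 0.03 (median 0.09, camera adjusted p = 4.72e-12, adjusted p = 0.0566 with an estimated correlation). Mitochondrially encoded mRNAs fell in 2 of 13 cases, MT-ND6 at −0.57 ± 0.08 and MT-ND4L at −0.29 ± 0.05 (median −0.08, camera adjusted p = 0.0132, adjusted p = 0.565 with an estimated correlation). Mitochondrial genes held 1.997%, 2.006% and 2.621% of counts before TMM scaling in TGF-β1 with II559 replicates 1, 2 and 3 and 2.24 to 2.31% in TGF-β1. Without TGF-β1 with II559 replicate 3, 11 of the 13 mitochondrial mRNAs fell (median −0.26, camera adjusted p = 9.72e-45), while the call as a set ended without replicate 1 (camera adjusted p = 0.283) or replicate 2 (camera adjusted p = 0.0854) of that group. Without replicate 3 of that group, 27 cell cycle genes fell and 1 rose, 28 cholesterol and fatty acid synthesis genes fell and 1 rose, 14 collagens fell and 2 rose, and 24 ribosomal protein mRNAs rose.

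The other lists were not called as a set with II559. TGF-β target and feedback genes had 3 rises and 4 falls in 31 (median −0.01, camera adjusted p = 0.684). Examples were RHOB at 0.22 ± 0.03, JUNB at 0.19 ± 0.03, LTBP2 at −0.20 ± 0.02 and LRRC15 at −0.18 ± 0.03. Contractile and cytoskeletal genes had 8 rises and 4 falls in 30 (median −0.00, mean 0.01, camera direction up, camera adjusted p = 0.726). Members included the smooth muscle actin ACTG2 at 0.24 ± 0.03, TPM2 at 0.13 ± 0.02 and vinculin (VCL) at −0.12 ± 0.03. Matrix glycoproteins and proteoglycans had 7 rises, the proteoglycan LUM at 0.22 ± 0.03, and 9 falls, FBN2 at −0.25 ± 0.03 and ACAN at −0.24 ± 0.05 (camera adjusted p = 0.0539). In the methionine cycle, one-carbon and polyamine list 2 rose and 1 fell, MTHFD1 at −0.21 ± 0.04, of 26, and of 26 NAD and nicotinamide genes NNMT rose and 2 fell, QPRT at −0.25 ± 0.05 (camera adjusted p = 0.214 and 0.684). ATF4 response genes had 2 rises, ATF4 at 0.16 ± 0.03 and VEGFA at 0.13 ± 0.03, and 4 falls, SLC7A1 at −0.14 ± 0.02 (camera adjusted p = 0.538). Oxidative stress genes had 2 rises and 5 falls, TKT at −0.17 ± 0.03 and NQO1 at −0.15 ± 0.03 (camera adjusted p = 0.293), and metallothionein and zinc genes 2 falls in 6, MT2A at −0.20 ± 0.04 (camera adjusted p = 0.122). Lineage and immediate-early factors had 4 rises, FOS, FOSB, EGR1 and JUN (0.31 ± 0.03), and 4 falls (median −0.05, mean 0.02, camera direction up with adjusted p = 0.0539). With GC and length corrected for, the lineage list was called up (6 rises and 2 falls, camera adjusted p = 0.000575), though its median was −0.03. With the same correction the metallothionein list was called down (camera adjusted p = 0.0177). Both calls used the preset correlation. Some libraries left out and the replicate block also gave the lineage list a call (camera adjusted p from 0.00486 to 0.0474). Matrix glycoproteins were called down with RLE scaling (camera adjusted p = 0.0262), without TGF-β1 replicate 1 (camera adjusted p = 0.0274) and without TGF-β1 with II559 replicate 3 (camera adjusted p = 0.000214), and identity genes without that last library (camera adjusted p = 0.00177). Adipogenic genes had 2 rises, fibroblast identity genes 3 rises, CCN5 at 0.36 ± 0.07, and 6 falls, IGFBP5 at −0.30 ± 0.03 and DPP4 at −0.25 ± 0.05, and YAP genes 2 rises and 4 falls, AXL at −0.14 ± 0.02 (camera adjusted p = 0.538, 0.122 and 0.538). Among inflammatory cytokine and NF-κB genes, edgeR called 0 of 21, with 6 at an unadjusted p under 0.05 and 0 called by DESeq2 and by limma-voom. IL33, the member with the smallest p, was at 1.15 ± 0.40. Of the markers of other cells, DSP fell by 0.17 ± 0.03, the pericyte list had 1 rise, NDUFA4L2, and 2 falls, and edgeR, DESeq2 and limma-voom each called 0 of 4 endothelial, 4 leukocyte and 6 melanocyte and Schwann cell markers, with 1, 0 and 0 at an unadjusted p under 0.05. Median, mean and camera direction differed in sign for NAD genes (0.00, −0.03, down), keratinocyte markers (0.02, 0.04, down), pericyte markers (−0.04, 0.06, up) and leukocyte markers (0.04, −0.05, down). These 5 marker lists had camera adjusted p of 0.538, 0.781, 0.684, 0.854 and 0.917.

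In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1920 of 17523 genes were called with II559, 996 higher and 924 lower, with a median size of 0.18 on the log2 scale (1.13-fold), and 13 and 22 of them changed at least 2-fold. With RLE scaling 43.1% of the called genes were higher, and with DESeq2 42.9%, so which direction has more genes is not settled. Adjusted over the list alone, the numbers of genes lower and higher were 32 and 1 for the cell cycle, 29 and 1 for cholesterol and fatty acid synthesis, 15 and 2 for interferon-stimulated genes, 14 and 0 for collagens, 14 and 1 for matrix proteases, 14 and 1 for lysosome genes and 8 and 0 for the unfolded protein response. They were 0 and 10 for p53 targets, 2 and 8 for glycolysis, 2 and 10 for oxidative phosphorylation, 0 and 22 for ribosomal protein mRNAs, 7 and 3 for TGF-β targets, 8 and 9 for contractile genes, 11 and 7 for matrix glycoproteins and 10 and 2 for collagen processing. For methylation enzymes they were 9 and 0, for the methionine cycle 4 and 3, for ATF4 genes 6 and 3, for oxidative stress 5 and 4, for YAP genes 5 and 5, for lineage factors 5 and 4, for adipogenic genes 1 and 2 and for identity genes 6 and 4, and the other lists did not change. Across genes of at least 3 on the log2 CPM scale, the fold change with II559 had a Spearman correlation of −0.258 with GC content and −0.302 with transcript length (genes are not independent replicates). With offsets for both they were −0.0276 and −0.0996, so part of the length trend was left, and 1403 genes were called with these offsets, 1174 of them among the 1920 and all 1174 with the same sign. The count was 961 at adjusted p under 0.01, 4 against a fold change of 1.5, 1185, 1204 and 1122 without TGF-β1 replicate 1, 2 or 3, and 2708 without TGF-β1 with II559 replicate 3.

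Whether II559 moved the TGF-β1 response back towards control was asked gene by gene. FOS had fallen with TGF-β1 (−1.32 ± 0.03, from 203 ± 2.06 CPM in control) and rose with II559 (0.87 ± 0.03), and FOSB (−1.61 ± 0.08 and 0.87 ± 0.08), ARHGAP28 (−2.94 ± 0.09 and 0.57 ± 0.11), EGR1 (−1.20 ± 0.05 and 0.46 ± 0.05) and the bone proteoglycan OMD (−2.85 ± 0.07 and 0.45 ± 0.07) had the same pattern. PRR11 rose with TGF-β1 (0.51 ± 0.08) and fell with II559 (−0.53 ± 0.08). Other genes moved further from control with II559: IFI6 (−1.34 ± 0.11 and −1.02 ± 0.13), the citron kinase gene CIT (−2.29 ± 0.07 and −0.79 ± 0.09), the keratin KRT19 (−2.22 ± 0.10 and −0.75 ± 0.13) and CEMIP, a hyaluronan-degrading factor that fell from 1741 ± 8.77 to 127 ± 1.33 and 84.5 ± 4.39 CPM.

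**Figure D3:**
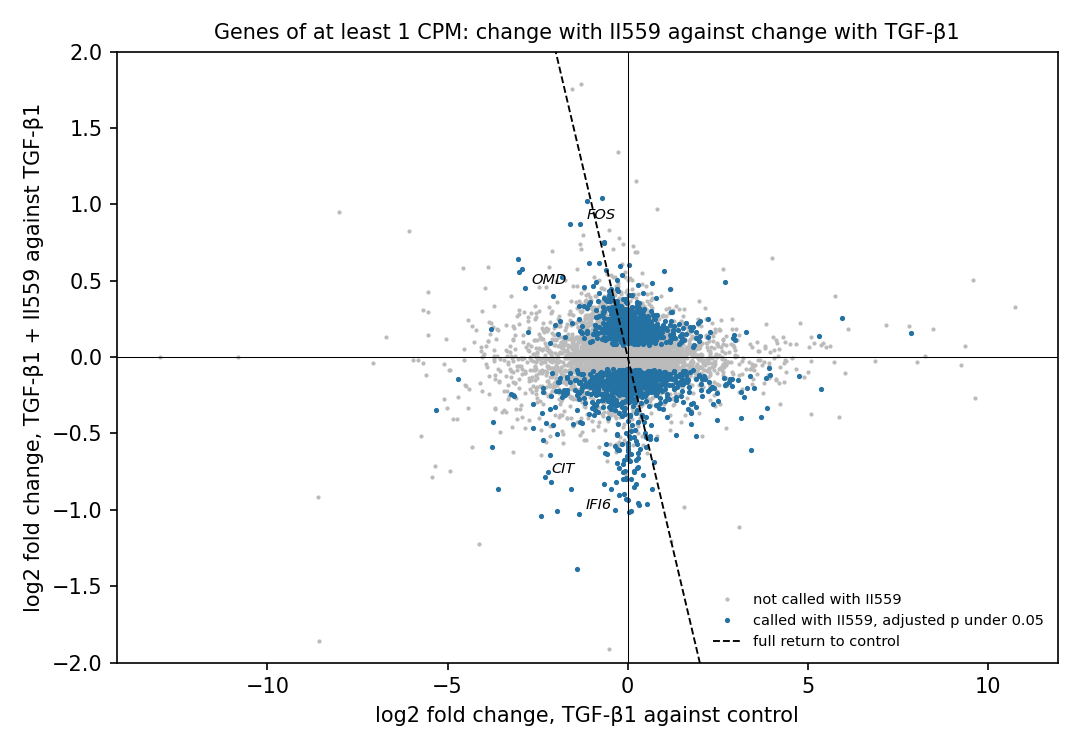
Log2 fold change with II559 in TGF-β1-treated cells (vertical) against log2 fold change with TGF-β1 (horizontal) for 13444 genes of at least 1 CPM, 3 of which lie outside the vertical axis, with 1878 genes called with II559 filled and a dashed line where a gene would be back at its control level. Most points lie along the horizontal line, and FOS lies toward the dashed line.

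Of the 12051 genes called with TGF-β1, 813 (6.75%) were also called in the opposite direction with II559 and 783 (6.50%) in the same direction, both by edgeR's quasi-likelihood test. Lists of these sizes drawn independently would share 661 opposite and 660 same. The 813 were 447 genes raised by TGF-β1 and lowered with II559 and 366 the other way, against 312 and 348 for independent lists. The 783 were 450 genes raised in both comparisons and 333 lowered in both, against 337 and 323. Against independent lists, genes raised by TGF-β1 were thus in excess in both directions. Such lists take every gene as equally easy to call, whatever its counts, so the excess cannot by itself be read as an effect of II559. Both comparisons use the same 3 TGF-β1 libraries with opposite signs. In 20 simulations with no II559 effect, a mean of 1.15 opposite and 0.25 same calls arose. These simulations held no GC or length trend between libraries. Such a trend alone, planted at a size not matched to these data, gave 732 calls without offsets. The simulated counts are thus no full reference for the 813 and 783. The Pearson correlation of the fold changes across genes was −0.0871, against −0.137 ± 0.0192 (SD of 20 simulations), and the covariance −0.0369 against −0.0531 ± 0.00834. Among genes above 1 on the log2 CPM scale the correlation was −0.0543, against −0.0580 ± 0.0281, and the covariance −0.00833 against −0.00497 ± 0.00271. Among genes changed at least 2-fold by TGF-β1 and above 1 on the log2 CPM scale, the change left with II559 was a median of 98.7% (quartiles 94.0 to 103%) for the 759 that rose and 101% (quartiles 95.4 to 108%) for the 816 that fell. Under 50% of the change was left for 4 genes: FOS (33.6%), FOSB (45.9%), and POLR2J2-UPK3BL1 (35.6%) and a gene without a symbol (45.5%), neither of them called with II559; the last 2 were singled out after their values were seen. The share called in the opposite direction was 3.62% at adjusted p under 0.01 and 4.34, 4.21 and 4.11% without TGF-β1 replicate 1, 2 or 3, and the correlation was −0.369 with no filter on low counts and −0.154, −0.166 and −0.200 without those libraries.

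TGF-β1 with II559 against control asked how far cells given both stand from untreated cells. By the same limits, KANK4, COMP and CHRNA9 were again the largest rises, 305-, 261- and 256-fold, and ADH1B (0 counts, at least 999-fold lower), SLC7A14 (−10.43 ± 0.72, from 36.7 ± 0.607 CPM to the few counts of 0.025 ± 0.0133 CPM) and COL21A1 (−7.09 ± 0.22) the largest falls. ACTA2 was 6.74-fold higher than in control, COL1A1 2.48-fold, FN1 2.85-fold and NNMT 5.44-fold, and MMP1 was 6.71-fold lower. TGF-β target genes rose in 26 of 31 cases, contractile genes in 28 of 30, collagens in 17 of 25, ATF4 genes in 34 of 36 and glycolysis genes in 27 of 30, while interferon-stimulated genes fell in 28 of 36 cases and fibroblast identity genes in 22 of 28. Cell cycle genes fell in 33 of 40 cases and rose in 2 (median −0.49, camera adjusted p = 0.0334, adjusted p = 0.0757 with an estimated correlation, and camera adjusted p = 0.0512 without TGF-β1 with II559 replicate 3). Cholesterol and fatty acid synthesis genes fell in 21 of 33 cases and rose in 8 (median −0.21, camera adjusted p = 0.0415, adjusted p = 0.184 with an estimated correlation, and camera adjusted p = 0.0579 with GC and length corrected for). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 12157 genes were called, 6161 higher and 5996 lower, with 4211 called against a fold change of 1.5, and 10850 were called in both comparisons with control, 10810 with the same sign. Adjusted over the list alone, the counts were the same for these lists except 29 interferon-stimulated genes lower.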

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

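The offsets for GC content and length, unrounded counts, upper quartile scaling of lists, both tests of the cause of the II559 calls, and the splits for TGF-β1 against control and for II559 were chosen after the results were seen. No called value turned its direction under any alternative. The counts of called genes stayed within 1.5 times the reported ones for all alternatives except these. Against a fold change of 1.5 they were 4129 for TGF-β1 against control, 4211 for both agents against control and 4 for II559. For II559, adjusted p under 0.01 gave 961 genes, and leaving out TGF-β1 replicate 1, 2 or 3 gave 1185, 1204 and 1122. Leaving out any other library gave 1609 to 2708, which is within that limit. The share of TGF-β1 genes called the opposite way with II559 was 3.62% at adjusted p under 0.01 and 4.11 to 9.17% leaving out 1 library. The correlation of the fold changes was −0.369 with no filter on low counts and −0.200 to −0.0494 leaving out 1 library. The lists called as a set fell from 18 to 9 (TGF-β1), 15 to 6 (II559) and 18 to 11 (both agents against control) with an estimated correlation, and fry, another question, called 32, 17 and 33. Of the 128 genes named for II559, 117 were called, and 20 of these lost their call with GC and length offsets, 20 with only the 2 groups compared, 22 or 23 without a TGF-β1 library, and 3 to 14 without a library of the II559 group. Apart from the collagen list, the cause of these shifts was not tested, except that a stricter threshold calls fewer genes by construction. With GC and length offsets 61.1% of the II559 calls stayed called with the same sign, although a correlation of −0.0996 with length was left. The cell cycle genes, which fell beyond lists of like GC content and length, argue against the trend as the whole cause of the calls. Without TGF-β1 with II559 replicate 3, 2708 genes were called, 1744 of them among the 1920 and with the same sign, so most calls do not rest on that library. At this depth changes of 0.2 on the log2 scale were recovered in 34% of simulated genes. The 6 libraries of a comparison can be split in 10 ways, too few for a share under 0.05. The real split, with 12051, 1920 and 12157 calls in the 3 comparisons, was the only 1 of the 10 with as many. The highest count of the other splits was 0 by edgeR, with up to 131, 1314 and 221 genes at an unadjusted p under 0.05. Every other split mixes the real groups, which widens the spread within its groups and makes few calls likely from the start. These splits are therefore no reference for chance, and no conclusion was drawn from them. Other tools were not run on the splits.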

Other observations

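Among the tests here, only that of the return towards control was chosen after its result was seen, while for the cell cycle and collagen lists the corrected medians had been seen before the tests were written. More zinc finger genes were seen to rise than to fall with II559, though most were not called: of 424 genes with a ZNF symbol and at least 1 CPM, edgeR called 32 higher and 4 lower with II559 in TGF-β1-treated cells. Their median log2 fold change was 0.06, and 97.6% of it was left with offsets for GC content and length, under which 22 were higher and 3 lower. The group was picked after its values were seen. Among all 17523 genes tested, 996 were called higher and 924 lower, and of 13444 genes of at least 1 CPM 1878 were called. The ZNF genes were thus called no more often than genes in general, and few of them fell.

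Mitotic and replication genes within the cell cycle list were counted apart, without a test of the difference between them. Of 22 mitotic genes such as MKI67, TOP2A and CCNB1, 20 fell, with a median of −0.69, and of 14 replication genes such as the MCM genes 6 fell, with a median of −0.21. TGF-β1 against control gave medians of 0.07 and −0.22 for the same genes.

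A GC and length trend accounts poorly for the cell cycle pattern: the list's median of −0.52 lay at percentile 0 of 10000 random lists matched on GC content, length and expression, 95% of whose medians lay between −0.04 and 0.06. Such lists take genes as independent, which cell cycle genes may not be. With offsets, camera also called the list at its estimated correlation (adjusted p under 0.05). A smaller share of cycling cells with II559 is a candidate explanation, under which both the replication and the mitotic members would be lower. The higher of their 2 medians was −0.21, below a limit of −0.1. That limit was set before these 2 medians, though after that of the whole list, had been seen, so this outcome was likely from the start. An effect on the genes themselves would also lower both medians, so the result favours neither explanation. If the lower median of the mitotic members holds, a shift between phases could also play a part. Neither cell numbers nor a group given II559 alone were available, so slower growth and an effect on these genes themselves stay open.

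The fall of collagen chains with II559 may in part be technical. Lists matched on GC content, length and expression had a median of −0.06 with II559 (95% of them between −0.10 and −0.02), while the collagens had −0.12, at percentile 0.07. Such lists take genes as independent, which the collagens are not (estimated correlation 0.335). With offsets camera called the list at its preset correlation (adjusted p = 0.000801) but not at the estimated one (adjusted p = 0.394, and 0.134 without offsets), so the trend and an effect of II559 cannot be told apart for this list, and no biological explanation was tested. With offsets the collagen median went from −0.12 to −0.05 and COL1A1 from −0.12 ± 0.02 to −0.05 ± 0.01, and in all 8 collagens that lost their call the change became smaller, to a median of 43.5% of its size, while the standard error stayed at a median of 103%.

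A general return of the TGF-β1 response towards control with II559 was tested by the slope of the II559 change on the TGF-β1 change over genes called with TGF-β1. A return of 10% or more would give a slope under −0.1, and the slope was −0.0133. It was −0.0254 in simulations with no II559 effect, where the shared TGF-β1 libraries alone make it negative. The observed slope lay outside the simulated range of −0.0355 to −0.0186, so these simulations are no full reference for it. Among called genes above 1 on the log2 CPM scale the slope was 0.00231, against −0.00484 in the simulations. The tables thus argue against a return of the response as a whole. They may still hold a return of single genes, such as FOS and FOSB.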
